A study of Mus musculus with 9 samples.

How the data were processed

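RNA was measured in the dissected mid-foregut of wild-type mouse embryos at 16-20, 21-25 and 26-30 somites, with 3 biological replicates per stage. Per the labels' protocols, 5 to 10 foreguts were pooled, the neural tube and the heart were removed during dissection, and 100 ng of total RNA went through 2 rounds of linear amplification, which gave 10 to 15 µg of biotin-labelled RNA. Amplification of this kind favours the 3' ends of transcripts, so signals of different probe sets of one gene can differ with RNA length. The authors made the deposited intensity values with MAS5, per the submitters' processing notes; its version, scaling target and detection calls are not given in the sources used here. The deposited intensities are on a linear scale, and the mean of each array after trimming 2% at each end lay between 500.2 and 500.3, as after scaling to a common target. Such scaling sets the average of an array and leaves its relative range of signal as it was. The number of arrays limits the precision. In limma, p-values of single genes measure the spread between pools, which includes differences between their arrays. List tests with a preset correlation, described below, also rest on that correlation.

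The table held 22690 probe sets, of which 64 were Affymetrix controls. The platform's annotation gave 1 gene symbol for 20380 of the others, several for 691 and none for 1555. Probe sets with several or no symbols were left out. Gene identifiers of 20351 probe sets matched a RefSeq gene table, which changed 0 symbols. A gene was represented by its probe set with the highest mean, which gave 12393 genes. Of the named genes tested, 50 had a second probe set above the filter, and in 21 of these a probe set had the other sign over the whole interval.

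Array medians lay within 0.30 log2 of each other, under the limit of 0.5 set for a further normalization, so values were used as deposited. Values were taken to log2 after adding a pseudocount of 26.2, the 20th percentile of all values. Genes with a mean under the 30th percentile of gene means were left out, which left 8675. Stage means were fitted to all 9 arrays in 1 model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), and contrasts were drawn for each step, for the whole interval, for the difference between the steps and, with the moderated F test, for any difference between the 3 stages. Tests were two-sided, and p was adjusted by Benjamini-Hochberg at 0.05. No pair of arrays held identical values (0 pairs), and correlations across genes, which are not independent replicates, were 0.901 to 0.981 within stages and 0.893 to 0.972 between them.

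Gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. They cover regulators and signalling pathways of the foregut, housekeeping complexes, and markers of neighbouring tissues that a dissected foregut could hold. Of 32 lists, 31 had at least 5 tested genes and were tested with camera of limma at a preset correlation of 0.01, and again with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Lists were adjusted together within a contrast. Among the lists called, the estimated correlation ran from 0.10 for WNT signalling to 0.61 for hepatic markers, above the preset 0.01. The named genes were up to 10 per direction past the threshold, or where fewer passed the 5 with the smallest p in each direction, then up to 4 members of each list with the widest change over the whole interval, and 32 genes of lung and foregut development or neighbouring tissue. A few further genes that passed adjusted over a list alone were named after their values were seen: Rdh10, Notch1, Fzd6, Rps24 and Rplp0, beside Myh6 for its signal in a single array.

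The limma step was tested on simulated values made from the means and spreads of the 8675 tested genes. In 20 simulated sets of the comparison of 26-30 with 16-20 somites, each with 200 genes changed, it recovered 40% of changes of 1 on the log2 scale, 90.4% of 1.5, 98.4% of 2 and 100% of 3, with 8.50 false calls on average. Camera found 20 of 20 simulated lists of 40 genes shifted by 0.5, at an unadjusted p under 0.05, and 2 of 20 unshifted ones. The simulation leaves out differences that many genes of an array share.

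Alternatives were quantile normalization, centring of each array on its median, a pseudocount of 6.55 or 105, no filter or a filter at the 50th percentile, eBayes without a trend, array weights, the replicate number as a block, the mean of all probe sets of a gene, only the 6 arrays of the compared stages, and leaving out each array in turn. Added after seeing the data were fits without the 3 arrays whose highest signal lay below the widest gap between arrays, with the 99th percentile of signal as a covariate, without those 3 arrays and 16-20 somites replicate 2, and without 21-25 somites replicates 1 and 2. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.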

Results

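Gene expression was measured in the mid-foregut of wild-type mouse embryos, the stretch of gut tube that lies behind the pharyngeal arches and in front of the liver and from which the lung buds grow. The embryos were staged by their number of somites, the paired blocks of mesoderm that are added one after another as the body axis extends. There were 3 groups, at 16-20, 21-25 and 26-30 somites, which the labels place at embryonic days 8.5, 9.0 and 9.5. Each group had 3 biological replicates, each replicate was a pool of 5 to 10 foreguts, and each pool was hybridised to 1 Affymetrix array after 2 rounds of RNA amplification. The spread between replicates is therefore that between pools, each with its array, and the number of arrays limits the precision of every value. The array had 22690 probe sets, 12393 genes had a probe set of their own, and 8675 genes passed the filter on low signal and were tested. Signals are given as the mean ± SD of the 3 arrays of a stage on the linear MAS5 scale, and changes as log2 differences ± SE from limma on log2(signal + pseudocount), a scale that understates the change of dim genes.

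Some arrays differed from others of the same stage. In 21-25 somites replicate 1 and 26-30 somites replicates 1 and 2 the highest signal lay between 27479.8 and 32584, against 43792 to 61749 in the other 6, and these are called the 3 narrow-range arrays. All of them are at 21-25 or 26-30 somites, so their range cannot be wholly told apart from stage. The control probe set for the 3' end of 18S ribosomal RNA read 274, 776 and 490 on these arrays, and 1264 to 3122 on the others. The ratio of the 3' to the 5' probe set of beta-actin, a measure of RNA length, was highest in 21-25 somites replicate 2, at 45.3, and between 20.9 and 36.8 elsewhere. The same ratio for Gapdh was highest in 26-30 somites replicate 3, at 40.9, against 36.4 in 21-25 somites replicate 2. The 3 narrow-range arrays had the lowest ratios for both genes, 20.9 to 22.2 for actin and 16.0 to 21.0 for Gapdh, and median spike-in signals of 409, 1316 and 839, against 1194 to 2176 on the others. Genes of the hepatic and cardiac marker lists stood out in 16-20 somites replicate 2. Transthyretin (Ttr) had a signal of 21558.6 there, against a mean of 1576 over the other arrays of that stage. The cardiac myosin heavy chain Myh6 had 5247 against 543.

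**Figure D1:**
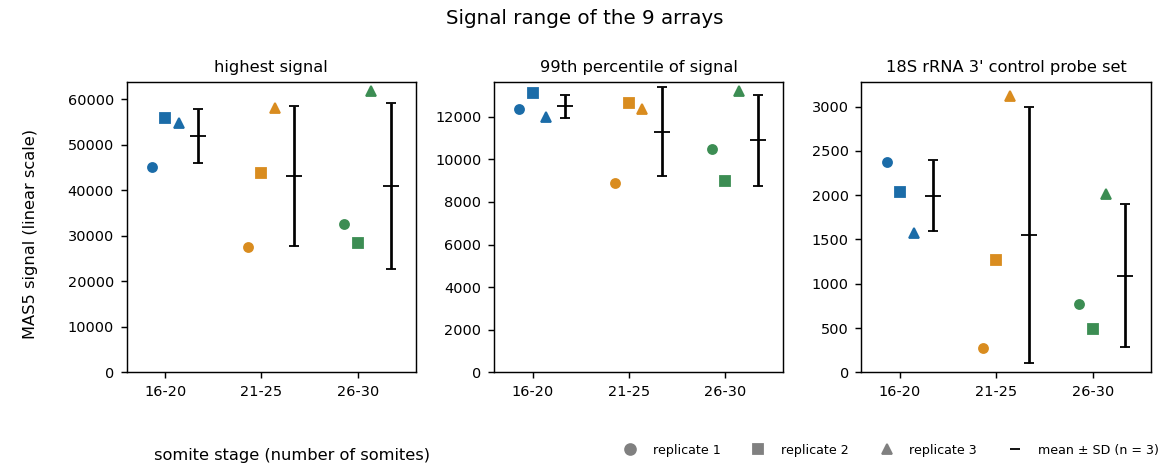
Highest MAS5 signal, 99th percentile of signal and signal of the 18S rRNA 3' control probe set (linear scale, from 0) for each array, by somite stage, with symbols for single arrays and bars for the mean ± SD of 3 arrays. The 3 narrow-range arrays have the lowest values in each panel, with 18S signals of 274, 776 and 490.

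The widest comparison, of 26-30 with 16-20 somites, asks which transcripts differ across the interval in which the lung buds are induced. Regulators of the foregut and lung mesenchyme, the loose tissue around the gut tube, were higher as a group at 26-30 somites, with a median log2 difference of 0.48 over 22 tested genes, 18 of them positive. Genes for cytosolic ribosomal proteins were lower, with a median of -0.55 and 40 of 43 genes negative, and so were genes of the mitochondrial respiratory chain, with a median of -0.43 and 47 of 54 negative. These calls assume a small preset correlation between genes, and each list had an adjusted p = 0.806 with an estimated correlation. The single genes with the largest support were Rnf157, a ubiquitin ligase, and St8sia4, a polysialyltransferase, both with larger signals in all 3 later arrays. None of these genes passed the test over all genes: by limma, 0 of 8675 genes had an adjusted p under 0.05, the smallest adjusted p was 0.219, and 967 genes had an unadjusted p under 0.05, where chance gives about 434.

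The mesenchymal genes furthest apart were transcription factors. Tbx5, a T-box factor of the heart and lung fields, had a signal of 116 ± 31.8 at 16-20 and 306 ± 57.1 at 26-30 somites, a log2 difference of 1.23 ± 0.47. Isl1, a LIM homeodomain factor, went from 973 ± 281 to 2087 ± 325, or 1.11 ± 0.29, and Hoxa5, a homeobox gene, from 103 ± 67.5 to 259 ± 59.6, or 1.31 ± 0.44. In all of these the 3 later arrays lay above the 3 earlier ones, and their adjusted p in limma was 0.375, 0.317 and 0.349. Twist1, a basic helix-loop-helix factor of mesenchyme, had a difference of the other sign, -0.90 ± 0.27. The list as a whole had an adjusted p of 5.58e-04 in camera of limma, and an adjusted p = 0.806 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Per array, the median deviation of this list was highest on the 3 narrow-range arrays, at 0.42, 0.28 and 0.32, and was 0.04 on 26-30 somites replicate 3. Without the 3 narrow-range arrays, which leaves 1 array of 26-30 somites that is assumed to vary like the others, the median was 0.32 with an adjusted p of 0.0147, and over all alternatives with the preset correlation the adjusted p ranged from 1.32e-04 to 0.0383. Fry gave 0.573.

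WNT signalling, chromatin and anterior Hox lists were higher at 26-30 somites in camera of limma. WNT signalling genes had a median of 0.28 with 24 of 32 positive and an adjusted p of 0.00591, and an adjusted p = 0.806 with an estimated correlation. Its widest differences were in the R-spondin gene Rspo2 (1.21 ± 0.43) and in the secreted frizzled-related gene Sfrp2 (1.16 ± 0.32). Genes of chromatin remodelling and modification had a median of 0.28 over 73 genes, 57 of them positive, with an adjusted p of 5.58e-04 and an adjusted p = 0.806 with an estimated correlation. Among them Pbrm1, a subunit of a SWI/SNF complex, had 1.16 ± 0.82, although its other probe sets gave -0.04 and -0.09, and Bmi1, a Polycomb component, had 1.11 ± 0.27. Anterior Hox genes, those of paralogue groups 1 to 5, had a median of 0.28 with 6 of 9 positive and an adjusted p of 0.0396, and an adjusted p = 0.806 with an estimated correlation. In that list 0 genes passed over all genes and 2 adjusted over the list alone, Hoxa4 (1.63 ± 0.42) and Hoxa5. Hoxa4 was dim, with a mean log2 signal of 6.74 against a filter level of 6.66. The Hox call ended under several settings: without 16-20 somites replicate 2 its adjusted p was 0.190, without 21-25 somites replicate 3 it was 0.0534, without 26-30 somites replicate 1 it was 0.0723 and with quantile normalization 0.0692. The Hox median without single arrays stayed between 0.23 and 0.34. It also ended without a filter (0.191), with the 50th percentile filter (0.571) and with the mean of all probe sets (0.123). These 3 lists also had their highest medians on the 3 narrow-range arrays, and on 26-30 somites replicate 3 they had 0.02 for WNT, -0.05 for chromatin and -0.07 for Hox genes. The WNT call ended without a filter (0.130) and with the mean of all probe sets (0.156), and its median was 0.17 without 16-20 somites replicate 2. The chromatin median was 0.42 without 26-30 somites replicate 3. Without the 3 narrow-range arrays the adjusted p was 0.135 for WNT signalling, 0.136 for chromatin with a median of 0.08, and 0.241 for Hox genes, and over the alternatives with the preset correlation the ranges were 0.00312 to 0.341, 2.43e-04 to 0.335 and 0.0193 to 0.627. Fry gave an adjusted p of 0.573 for each of the 3 lists.

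The lower lists were led by ribosomal proteins, with an adjusted p of 1.57e-12 in camera of limma and an adjusted p = 0.806 with an estimated correlation. Rps15 had a signal of 3782 ± 1140.1 at 16-20 and 1802 ± 871 at 26-30 somites (-1.12 ± 0.38), and Fau 4554 ± 1165 and 2062 ± 444 (-1.12 ± 0.43). Rpl41 had the widest difference, -3.22 ± 0.55, and was the 1 ribosomal gene that passed adjusted over the list alone, against 0 over all genes. Its probe sets disagreed, with -1.52, -0.10 and 0.29 in the other 3. Respiratory chain genes had an adjusted p of 2.91e-07 and an adjusted p = 0.806 with an estimated correlation, and Atp5k, a subunit of ATP synthase, went from 6343 ± 2254 to 2637 ± 864 (-1.25 ± 0.40). Both lists had their lowest medians on the 3 narrow-range arrays. Without these the median was -0.18 for ribosomal proteins, with an adjusted p of 0.0147, and -0.13 for the respiratory chain, with an adjusted p of 0.223. Without 26-30 somites replicate 2 the respiratory chain median was -0.29, and with quantile normalization the ribosomal median was -0.30. Over the alternatives with the preset correlation the adjusted p ranged from 6.65e-17 to 0.104 for ribosomal proteins and from 4.11e-10 to 0.335 for the respiratory chain, and fry gave 0.573 for both.

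Cardiac muscle markers had a median of -0.45 with 15 of 20 genes negative and an adjusted p of 0.0112 in camera of limma, and hepatic markers a median of -0.80 with 9 of 12 negative and an adjusted p of 0.0174. Both gave an adjusted p = 0.822 with an estimated correlation. Tnni1, a slow troponin I expressed in the embryonic heart, went from 818 ± 520.0 to 257 ± 69.3 (-1.42 ± 0.37) and was the 1 cardiac gene that passed adjusted over the list alone, with 0 over all genes. Ttr went from 8237 ± 11553 to 588 ± 276 (-2.66 ± 0.85). Without 16-20 somites replicate 2, the array with high signals of these markers, the medians were -0.04 and -0.05 and the adjusted p 0.759 and 0.423. The cardiac call also ended without 26-30 somites replicate 2, at an adjusted p of 0.170, and the hepatic call without 26-30 somites replicate 3, at 0.134, while the hepatic median was -1.21 without 16-20 somites replicate 1. Without a filter the cardiac adjusted p was 0.0635, with array weights the cardiac and hepatic values were 0.304 and 0.0520, and over the alternatives with the preset correlation they ranged from 6.78e-05 to 0.759 and from 3.83e-04 to 0.423. Fry gave 0.740 for both lists.

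**Figure D2:**
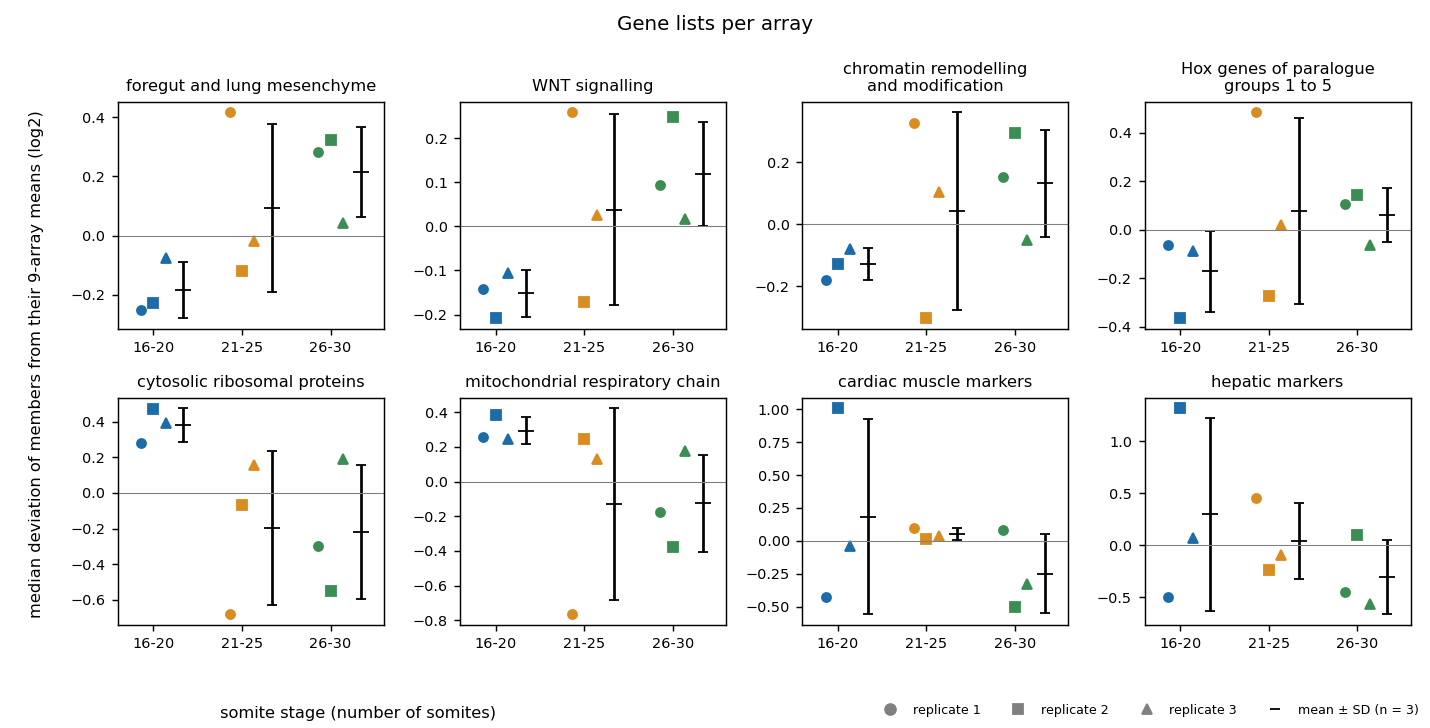
Median deviation of the members of 8 gene lists from their means over the 9 arrays (log2), for each array by somite stage, with symbols for single arrays and bars for the mean ± SD of 3 arrays. The ribosomal and respiratory chain medians are lowest in 21-25 somites replicate 1, and the cardiac and hepatic medians are highest in 16-20 somites replicate 2.

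Over all tested genes, the 5 genes with the smallest p in each direction gave values that did not pass. Rnf157 had a signal of 217 ± 54.0 at 16-20 and 795 ± 195 at 26-30 somites (1.75 ± 0.27), and St8sia4 555 ± 284 and 2396 ± 349 (2.18 ± 0.37). The amino acid transporter Slc38a5 had a log2 difference of 1.77 ± 0.32, cyclin D2 (Ccnd2) 1.12 ± 0.23, and the transcription factor Ets1 1.68 ± 0.34, where its other probe sets gave 1.498 and, in a dim one, -0.08. On the lower side, beside Rpl41, were Galnt3, an enzyme of O-glycosylation (-1.63 ± 0.30), and the potassium channel Kcnh3 (-1.62 ± 0.32). Kazald1 (-1.20 ± 0.23) and Haus1, a part of the augmin complex of the spindle (-1.19 ± 0.24), were also lower. Kcnh3 and Kazald1 were dim, with mean log2 signals of 6.97 and 6.87 against a filter level of 6.66. The 3 arrays of one stage lay wholly above those of the other for 1850 genes, or 21.3%, where chance gives 10% for a single gene. Genes share differences between arrays, so the share over all genes can lie far from 10% without a difference between stages. The count of 0 changed with the fit. When arrays were weighted by their spread around the stage means, limma called 731 genes, 414 higher and 317 lower. Among them were all genes named so far in this paragraph, with adjusted p from 0.00200 (Rnf157) to 0.0129 (Ets1). Weights ran from 0.335 in 21-25 somites replicate 2 to 3.38 in 26-30 somites replicate 1, a narrow-range array. At 26-30 somites, replicate 2, also narrow-range, had 1.34, and replicate 3 had 0.67. Limma called 4 genes (Rnf157, St8sia4, Crabp1 and Rpl41, each with an adjusted p of 0.0442) when only the 6 arrays of both stages entered the fit. Leaving out a single array gave at most 1 gene: Rgs16, an inhibitor of G protein signalling, without 16-20 somites replicate 1 (2.29, adjusted p of 0.0413), and Rpl41 without 26-30 somites replicate 3 (-3.93, adjusted p of 0.0125). The count of genes at an unadjusted p under 0.05 was 600 without 16-20 somites replicate 2, 499 without 26-30 somites replicate 1, 486 without 26-30 somites replicate 2 and 281 without the 3 narrow-range arrays.

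The first step, of 21-25 with 16-20 somites, asks what differs before the last stage is reached. Ribosomal protein genes were already lower at 21-25 somites, with a median log2 difference of -0.51 and 39 of 43 genes negative, and so were respiratory chain genes, with a median of -0.43. Epithelial markers were also lower, with a median of -0.29 and 14 of 18 negative, led by the keratins Krt18 (3636 ± 1625 at 16-20 and 1317 ± 185 at 21-25 somites, -1.37 ± 0.30) and Krt19 (-0.93 ± 0.31). Mesenchymal markers and neural and neural crest markers were higher, each with a median of 0.33. Each of these lists had an adjusted p = 0.711 with an estimated correlation. By limma, 0 genes had an adjusted p under 0.05, the smallest adjusted p was 0.317, and 960 genes had an unadjusted p under 0.05; weighting the arrays also gave 0. The unadjusted count was 589 without 16-20 somites replicate 2. The arrays of both stages were wholly apart for 14.2% of genes, where chance gives 10% for a single gene. Without 21-25 somites replicate 3, limma called 3 genes, the proteasome gene Psmd13 (-2.56, adjusted p of 0.0118) and the splicing genes Sf3b5 (-2.96, adjusted p of 0.00341) and Sugp2 (1.99, adjusted p of 0.0490), and without 16-20 somites replicate 1 it called Rgs16 (2.32, adjusted p of 0.0372).

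In camera of limma 8 lists were higher and 4 lower at this step, and 0 of these calls held with an estimated correlation, where each list gave an adjusted p = 0.711 with an estimated correlation. The adjusted p was 1.93e-11 for ribosomal proteins, 2.23e-07 for the respiratory chain, 0.0135 for epithelial markers, 0.0122 for mesenchymal markers and 0.0119 for neural and neural crest markers. Erythroid markers were lower, with a median of -0.21 and an adjusted p of 0.0299. The other higher lists were anterior Hox genes (0.50, with 9 of 9 positive), foregut and lung mesenchyme (0.35), Notch signalling (0.30), extracellular matrix (0.24), chromatin (0.17) and WNT signalling (0.15), with adjusted p from 0.0135 to 0.0350. Against 0 over all genes, 8 ribosomal protein genes passed adjusted over the list alone, among them Rps24 (-1.18 ± 0.28) and Rplp0 (-0.72 ± 0.23), as did the receptor gene Notch1 (1.23 ± 0.29), Krt18 and the WNT receptor gene Fzd6 (0.99 ± 0.23). Without 21-25 somites replicate 1, a narrow-range array, 2 lists passed: ribosomal proteins (-0.33, adjusted p of 2.48e-04) and epithelial markers (-0.40, adjusted p of 0.00243), and the other 10 had adjusted p from 0.0652 to 0.470. The medians without it were 0.32 for neural and -0.20 for erythroid markers, close to those with it, and 0.27 for Hox, 0.17 for Notch, 0.14 for mesenchymal, 0.12 for foregut mesenchyme, 0.05 for WNT, 0.05 for matrix and -0.08 for respiratory chain genes. The epithelial call ended without 21-25 somites replicate 2, the array with the highest actin ratio, at a median of -0.10 and an adjusted p of 0.370. Without 16-20 somites replicate 2, mesenchyme, WNT, Notch, Hox, chromatin and neural lists had adjusted p from 0.0518 to 0.135, without 16-20 somites replicate 1 WNT, Notch, matrix and erythroid lists from 0.0600 to 0.236, and without 21-25 somites replicate 3 WNT, Notch, chromatin and erythroid lists from 0.0854 to 0.157. Without 21-25 somites replicate 2 several medians lay further from 0, as for mesenchymal (0.60), neural (0.55), chromatin (0.37) and erythroid genes (-0.55), and without 21-25 somites replicate 1 the chromatin median was 0.00. Quantile normalization ended the erythroid call (0.0677), as did array weights (0.0601), which also ended the epithelial one (0.0509). The WNT call ended without a filter (0.0813) and with the mean of all probe sets (0.135), and the Notch and Hox calls with the 50th percentile filter (0.0530 and 0.0659). Fry gave adjusted p from 0.548 to 0.599 for the 12 lists.

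Of the genes with the smallest p at the first step, Lifr, the receptor for leukaemia inhibitory factor, had a signal of 356 ± 56.9 at 16-20 and 981 ± 147 at 21-25 somites (1.40 ± 0.25). The tetraspanin Cd82 had 1.83 ± 0.34, although its other probe set gave -0.59, and Rnf157 had 1.34 ± 0.27. The transcription factor genes Zbtb1 and Rfx5 had 1.33 ± 0.26 and 1.31 ± 0.25. With the other sign were Aqp3, a water and glycerol channel (131 ± 36.5 and 34.4 ± 7.50, -1.36 ± 0.26), the mitochondrial ribosome genes Mrps35 (-1.05 ± 0.21) and Mrpl12 (-1.23 ± 0.27), Krt18 and Rpl41. All had an adjusted p of 0.317 in limma.

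The second step, of 26-30 with 21-25 somites, compares the later stages, when lung buds form. Erythroid markers were higher at 26-30 somites, with a median log2 difference of 0.50 and 14 of 17 genes positive, and Hemgn, a nuclear protein of blood progenitors, went from 226 ± 103 to 607 ± 271 (1.32 ± 0.37). Epithelial markers were higher, with a median of 0.37 and 13 of 18 positive, while extracellular matrix and mesenchymal markers were lower, with medians of -0.14 and -0.13. Each of these lists had an adjusted p = 0.914 with an estimated correlation. Twist1 went from 347 ± 120.4 to 130.2 ± 30.8 (-1.22 ± 0.27) and the mesodermal homeobox gene Meox1 from 581 ± 179.7 to 262 ± 40.8 (-1.04 ± 0.27). By limma, 0 genes had an adjusted p under 0.05 and the smallest adjusted p was 0.975. An unadjusted p under 0.05 was found for 353 genes, below the 434 that chance gives. With weighted arrays limma called 29 genes, 11 higher and 18 lower. Among them were Hemgn (adjusted p of 0.0420), Twist1 and Meox1 (both 0.0337). The unadjusted count was 782 without 21-25 somites replicate 1, 193 without 26-30 somites replicate 1 and 225 without 26-30 somites replicate 2. The arrays of both stages were wholly apart for 9.35% of genes, where chance gives 10% for a single gene.

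The adjusted p in camera of limma was 1.04e-05 for erythroid, 0.0309 for epithelial, 0.0309 for matrix and 0.0383 for mesenchymal genes, and each gave an adjusted p = 0.914 with an estimated correlation. Against 0 over all genes, Hemgn and the red cell anion exchanger Slc4a1 (1.12 ± 0.32) passed adjusted over the erythroid list alone, and Twist1 and Meox1 over the mesenchymal list alone. The erythroid medians per array ranged from -0.41 in 21-25 somites replicate 1 to 0.67 in 26-30 somites replicate 3. Without the first of these arrays the adjusted p was 0.0566, and without the second 0.0915, at medians of 0.31 and 0.23. The epithelial call ended without 21-25 somites replicate 2 (0.06, adjusted p of 0.468), 26-30 somites replicate 1 (adjusted p of 0.0594) or 26-30 somites replicate 3 (adjusted p of 0.0633). The matrix and mesenchymal medians turned to 0.05 and 0.11 without 21-25 somites replicate 1, both with an adjusted p of 0.838. Without 26-30 somites replicate 3 their adjusted p was 0.101 and 0.289, and without 21-25 somites replicate 3 it was 0.0507 and 0.0715. Without 21-25 somites replicate 2 their medians were -0.29 and -0.32, and the mesenchymal median was 0.02 without 26-30 somites replicate 3. The epithelial median was 0.57 without 21-25 somites replicate 1. Without a filter and with array weights the epithelial, matrix and mesenchymal calls ended, with adjusted p from 0.0845 to 0.367, and the erythroid adjusted p ranged from 2.73e-12 to 0.0915 over the alternatives with the preset correlation. The epithelial call also ended with the 50th percentile filter (0.193) and the mean of all probe sets (0.105), and the mesenchymal call with the mean of all probe sets (0.165) and the smaller pseudocount (0.0508). Fry gave an adjusted p of 0.944 for each of the 4 lists.

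Among genes with the smallest p at the second step, Rcan2, a regulator of calcineurin, had a signal of 695 ± 54.1 at 21-25 and 1453 ± 126 at 26-30 somites (1.04 ± 0.22), Aqp3 had 1.14 ± 0.26, Trappc12 1.32 ± 0.35, Popdc3 1.01 ± 0.26 and Lamtor1 0.82 ± 0.22. The centriolar gene Cetn3 had -1.09 ± 0.22, Kazald1 -1.02 ± 0.23 and Amot, which encodes angiomotin, -0.89 ± 0.20, with -0.09 in its other probe set. All had an adjusted p of 0.975 in the unweighted fit of limma. With array weights Rcan2, Cetn3 and Kazald1 had an adjusted p of 0.0337 and Amot of 0.0475 in limma. Aqp3, Trappc12, Popdc3 and Lamtor1 did not pass in that fit. Aqp3, Popdc3 and Kazald1 were dim, with mean log2 signals of 6.74, 6.83 and 6.87 against a filter level of 6.66.

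Genes chosen in advance for their part in lung and foregut development gave values that did not pass at any step in the unweighted fit. With array weights 6 of them had an adjusted p under 0.05 in limma over the whole interval. They were Isl1 (0.0173), Tbx5 and Sox2 (both 0.0228), Aldh1a2 (0.0358), Hoxa5 (0.0360) and Barx1 (0.0425). In that fit the narrow-range arrays of 26-30 somites had weights of 3.38 and 1.34, against 0.67 for replicate 3. Sox2, a transcription factor of the dorsal foregut endoderm, had a signal of 383 ± 238 at 16-20, 628 ± 200.02 at 21-25 and 730.1 ± 112 at 26-30 somites, with a log2 difference over the whole interval of 1.04 ± 0.37. Aldh1a2, which encodes an enzyme that makes retinoic acid, had 1.05 ± 0.39, and Barx1, a stomach mesenchyme gene, 0.70 ± 0.30. Hhip, which encodes a protein that binds hedgehog ligands, had 95.1 ± 18.5 at 21-25 and 198 ± 10.1 at 26-30 somites (0.89 ± 0.30). Wnt2, a ligand gene of the lung mesenchyme, had 1129 ± 252, 670.1 ± 21.8 and 1010.3 ± 114, or -0.71 ± 0.22 at the first step and 0.57 ± 0.22 at the second. Foxa2, an endodermal forkhead gene, had -0.33 ± 0.22 and 0.48 ± 0.22. Over the whole interval the hedgehog receptor gene Ptch1 had 0.33 ± 0.24, Gli1 0.30 ± 0.35, Bmp4 0.47 ± 0.34, Id2 0.32 ± 0.38, Gata6 -0.13 ± 0.22, Rarb 0.21 ± 0.24, Hoxb5 0.28 ± 0.23 and Fgfr2 0.30 ± 0.26, with -0.07 in a dimmer Fgfr2 probe set. The neighbouring tissue markers Alb, Actc1 and Myl7 had -0.27 ± 0.35, -0.32 ± 0.59 and -0.89 ± 0.63, Afp -1.31 ± 0.82, and the embryonic globins Hbb-bh1 and Hba-x -0.52 ± 0.58 and 0.23 ± 0.52. Other Afp probe sets gave -2.67 and -2.29.

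Nkx2-1, Shh, Wnt2b, Fgf10, Tbx4, Foxf1, Sox9 and Sftpc lay under the filter on low signal and were not tested. Nkx2-1, the factor that marks the lung and thyroid endoderm, had a signal of 31.1 ± 19.5, 52.4 ± 41.4 and 20.2 ± 11.3 at the 3 stages, Shh 23.3 ± 16.4, 11.4 ± 6.30 and 8.20 ± 12.4, and Foxf1, a forkhead gene of the gut mesenchyme, 15.7 ± 2.74, 17.8 ± 2.69 and 33.9 ± 27.1, where the filter corresponded to a signal of about 75.1. At these levels the arrays could not show whether such genes differed.

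**Figure D3:**
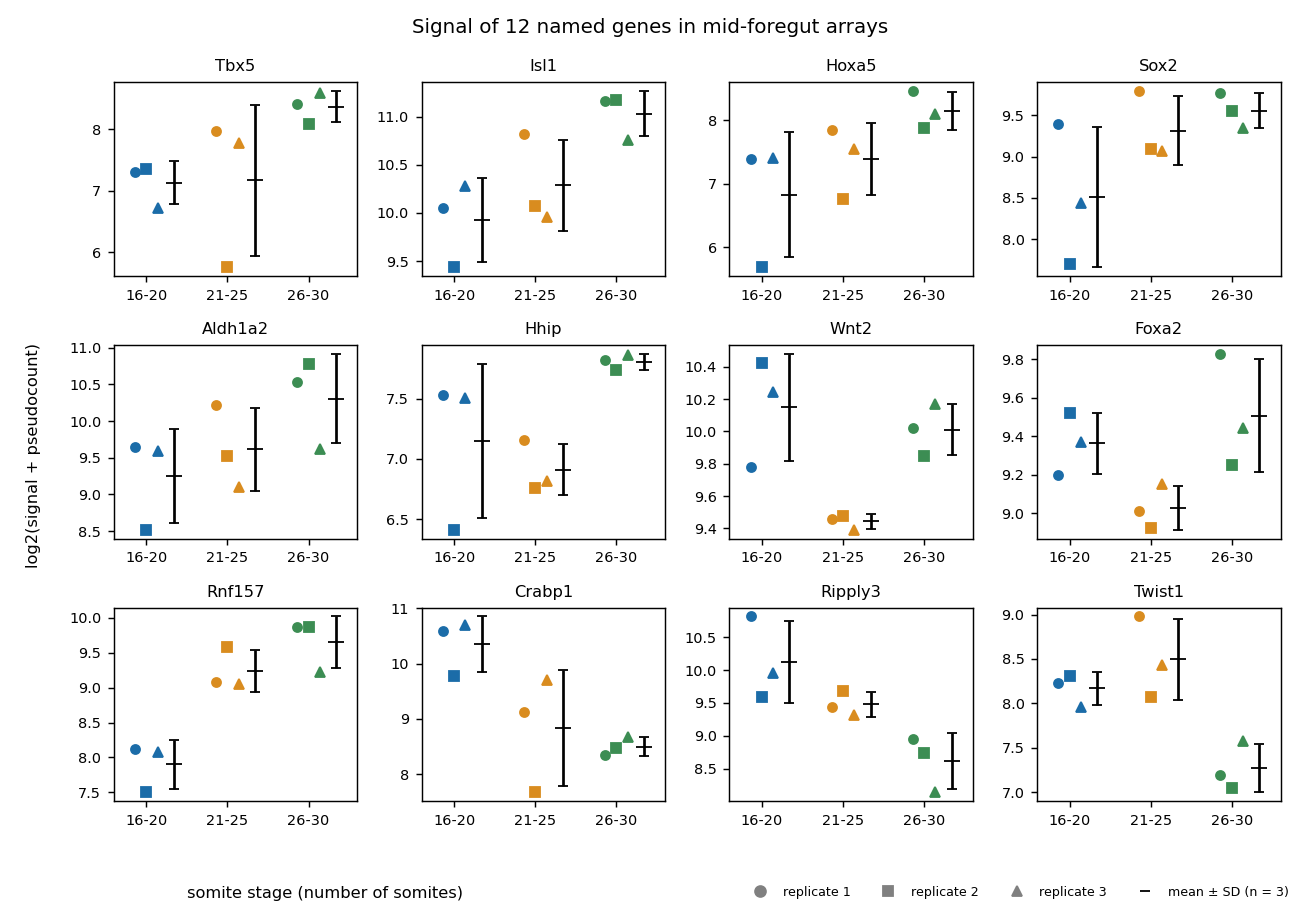
Log2(signal + pseudocount) of 12 named genes in each array, by somite stage, with axes that differ between panels and do not start at 0, symbols for single arrays and bars for the mean ± SD of 3 arrays. For Tbx5, Isl1 and Hoxa5 the 3 arrays at 26-30 somites lie above the 3 at 16-20 somites, with log2 differences of 1.23, 1.11 and 1.31.

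Whether a gene behaved differently in the 2 steps was tested directly. Wnt2 and Aqp3, whose values had opposite signs at the steps, did not pass: by limma, 0 genes had an adjusted p under 0.05 for the difference between the steps, the smallest adjusted p was 0.587, and 548 genes had an unadjusted p under 0.05. Likewise 0 genes differed between any of the 3 stages in the F test of limma, where the smallest adjusted p was 0.396 and 847 genes had an unadjusted p under 0.05. Weighting the arrays gave 0 genes for the difference and 339 for the F test, and without 21-25 somites replicate 3 limma called Psmd13, Sf3b5 and Sugp2 for the difference and 2 genes in the F test. Without 26-30 somites replicate 3 the F test called 1 gene. Its unadjusted count was 504 and 535 without 16-20 somites replicates 2 and 3 in turn, and 511 and 532 without 26-30 somites replicates 1 and 2 in turn. For the difference between the steps it was 838 without 21-25 somites replicate 3.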

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

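The explanation by narrow-range arrays and the splits counted at an unadjusted p were tests chosen only after the result was seen. The other regroupings were set before. The prediction for the matched random lists was written before they were drawn, but it concerns the ribosomal change that it is meant to explain. Gene lists whose change differed between the 2 steps were picked out by a test of the difference itself, the second step minus the first, in camera of limma. Ribosomal proteins differed by a median of 0.51 on the log2 scale (adjusted p of 4.29e-05), erythroid markers by 0.90 (1.46e-04), epithelial markers by 0.60 (0.00163) and respiratory chain genes by 0.42 (0.00163). The change was lower at the second step for mesenchymal markers, by a median of -0.44 (0.00173), extracellular matrix at -0.41 (0.00163), Notch signalling at -0.43 (0.0200) and neural and neural crest markers at -0.42 (0.0216). All 8 gave an adjusted p = 0.765 with an estimated correlation. Both steps share the 21-25 somite arrays, and the differences were not refitted without single arrays. Of these, replicate 1, a narrow-range array, had ribosomal, respiratory chain and erythroid medians of -0.68, -0.77 and -0.41. Its mesenchymal, matrix and Notch medians were 0.58, 0.47 and 0.56. Replicate 2 had -0.70 for epithelial markers. Without replicate 1 the medians at the 2 steps were 0.14 and 0.11 for mesenchymal and 0.05 and 0.05 for matrix genes.

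Ribosomal protein and respiratory chain genes were lower at 26-30 than at 16-20 somites, and 2 of the 3 later arrays were narrow-range arrays; the list calls had an adjusted p = 0.806 with an estimated correlation. For the ribosomal list, genes of like mean signal argue against a narrower range of signal that acts on all bright genes alike. The list's median of -0.55 lay at percentile 0 of 10000 random lists matched on mean signal, whose median was -0.06 and lowest value -0.29. These lists were drawn gene by gene, while ribosomal genes had an estimated correlation of 0.52. The percentile therefore overstates how rare -0.55 is, and the comparison shows only that genes of like signal did not fall as far. The respiratory chain list was not compared with such random lists. A difference particular to the narrow-range arrays remains a candidate explanation for most of the change in both lists. Without the 3 arrays a share of 0.329 of the ribosomal median was left (-0.18). The 95% range over resampled genes, which are not independent, was 0.124 to 0.508. For the respiratory chain the share left was 0.301 (-0.13). For ribosomal proteins, other values count against these arrays as the whole of the difference. The 3 later arrays that are not narrow-range had medians of -0.07, 0.16 and 0.19, below all 3 arrays of 16-20 somites (0.28 to 0.47). Chance separates 3 arrays from 3 in 10% of cases. Of the later arrays, 21-25 somites replicate 2 (-0.07) had the highest 3' to 5' ratio for actin, 45.3. The highest for Gapdh, 40.9, was in 26-30 somites replicate 3 (0.19), so RNA length is not separated from stage in these. In 21-25 somites replicate 3 (0.16) the ratios were 22.4 and 21.6. The first-step median was -0.33 without the narrow-range arrays and -0.31 with the 99th percentile as a covariate. With the covariate it was -0.33 over the whole interval. Camera called these at the preset correlation, and gave the first-step list an adjusted p = 0.711 with an estimated correlation. For the respiratory chain the same later arrays had 0.25, 0.13 and 0.18, not all below those of 16-20 somites (0.24 to 0.38). Its first-step median was -0.08 without 21-25 somites replicate 1, and its call over the whole interval ended with the covariate. Without the narrow-range arrays 26-30 somites has 1 array, and a difference between stages stays open.

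Groupings of the arrays were used to ask whether chance could give the counts. The real grouping is itself included in each count of splits or regroupings. Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. A count of 0 genes is reached by every split, 10 of 10 in each comparison, and so says nothing about chance; the highest other split gave 0 at the first step, 217 at the second and 0 over the whole interval. At an unadjusted p under 0.05 the real counts were 960, 353 and 967, and the highest other splits gave 817, 1776 and 542. The split with 217 genes parted the 3 narrow-range arrays from the other arrays of 21-25 and 26-30 somites. This points to a structure of the samples other than the grouping by stage, although the narrow-range arrays are spread unevenly over the stages. For lists, 2 of 10 splits gave as many as the 12 of the first step (highest other 14), 7 of 10 as many as the 4 of the second (highest other 9) and 1 of 10 as many as the 8 of the whole interval (highest other 6). Over all 9 arrays, the 0 genes of the F test and of the difference between steps are likewise reached by 100 of 100 regroupings drawn, which decides nothing; the highest other counts were 438, with the narrow-range arrays as one group, and 89. At an unadjusted p under 0.05 the F test gave 847 genes, 5 of 100 regroupings gave as many and the highest other gave 1812, so chance is not excluded. With array weights, 14 of 100 regroupings gave as many as the 339 genes of the F test. The highest other gave 1369, again with the narrow-range arrays as a group, so chance is not excluded for the count with weights. No regrouping count is given for the 731 genes called with weights over the whole interval.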

How the results depend on the processing

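Fits described as added were chosen after seeing the data; all others were set before. The count of 0 genes in limma stayed 0 for all 5 gene counts under quantile normalization, median centring, both other pseudocounts, both other filters, eBayes without a trend, the mean of all probe sets and the replicate block; the unadjusted counts over the whole interval ranged from 775 with the 50th percentile filter to 1234 with none. Array weights gave 29 genes at the second step, 731 over the whole interval and 339 in the F test, in place of 0. With only the 6 arrays of both stages, 4 genes passed over the whole interval. Leaving out each array in turn gave 0 to 3 genes at the first step, 0 at the second, 0 to 1 over the whole interval, 0 to 2 in the F test and 0 to 3 for the difference between steps; the genes, named after their values were seen, were Psmd13, Sf3b5 and Sugp2 without 21-25 somites replicate 3, Rgs16 without 16-20 somites replicate 1 and Rpl41 without 26-30 somites replicate 3 (the last 2 over the whole interval, Rgs16 also at the first step). In the added fits, the first step gave 1 gene (Rpl41) without the 3 narrow-range arrays; with the 99th percentile as a covariate it was 1 at the first step, 1 over the whole interval (Rpl41 in both) and 1 in the F test; without 21-25 somites replicates 1 and 2 it was 1 at each step and 1 for the difference between steps (Rhbdd3 in all 3, tested on 1 array of 21-25 somites that is assumed to vary like the others), 1 in the F test and 4 over the whole interval.

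Lists were 0 at each step and over the whole interval with an estimated correlation, and 0 likewise with fry. Leaving out each array gave 2 to 13 lists at the first step, 1 to 9 at the second and 5 to 9 over the whole interval. No filter gave 1 list at the second step and 5 over the whole interval. Without the narrow-range arrays 2, 2 and 5 lists passed at the first step, the second step and the whole interval, with the covariate 4 at the first step and 5 over the whole interval, and without these arrays and 16-20 somites replicate 2 it was 4 at the first step and 3 over the whole interval. Fits that left out arrays rest on fewer arrays, and for the other fits the cause was not tested. The direction of the camera test turned, with a call in the other direction, for 3 lists not called with all arrays. These were the respiratory chain, with a median of 0.21 at the second step without 21-25 somites replicate 2 (range without single arrays -0.33 to 0.21), where the median was already 0.04 and the mean -0.05 with all arrays, ribosomal proteins 0.18 at the second step without 26-30 somites replicate 2 (range -0.27 to 0.18), from a median just under 0, and cardiac markers 0.21, from -0.17, at the first step without the narrow-range arrays and 16-20 somites replicate 2. Of list values, 2172 stayed on their side of the threshold, 172 lost and 59 gained a call; of 11007 values of named genes, 465 had another sign. Same-numbered arrays of different stages had residual correlations from -0.284 to 0.257, 3 of 9 over 0.1, and 2 arrays correlated best with their own number. These values show no regular pairing by number, and 9 pairs are too few to exclude a pairing. The replicate block gave 0 genes and 12, 4 and 8 lists. Genes near or under a signal of 75.1 are limited by the background of the array.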

Other observations

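The tests on the cardiac and hepatic signals and on the Y-linked genes in this part were chosen only after the results were seen. Genes of retinoic acid handling had values of both signs over the whole interval. Crabp1, which encodes a cellular retinoic acid-binding protein, went from 1329 ± 419 at 16-20 to 338 ± 41.8 at 26-30 somites (-1.85 ± 0.43), Crabp2 from 882 ± 85.3 to 482 ± 159 (-0.88 ± 0.28), and Rdh10, a retinol dehydrogenase, had -0.65 ± 0.21. These 3 passed adjusted over the list alone in limma and 0 passed over all genes, and the list did not pass (median 0.02, mean -0.10, a negative direction and an adjusted p of 0.691 in camera). Gut hormone genes went opposite ways: Gcg, the glucagon gene, had 65.7 ± 10.97 and 242 ± 121 (1.46 ± 0.31), and Pyy 500.2 ± 133 and 236 ± 64.9, both past the threshold adjusted over the pancreas and posterior gut list alone. Ripply3, a repressor gene of the pharyngeal region, went from 1165 ± 541 to 377 ± 109.9 (-1.51 ± 0.32) and Tbx1, its pharyngeal neighbour in the list, had -0.58 ± 0.23.

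Cell cycle genes as a list had a median of 0.06 over 55 genes, and Birc5, which encodes survivin, had -1.18 ± 0.26 where Ccnd2 had 1.12 ± 0.23. Among genes of the early embryo, Hmga2 had 6951 ± 1943 and 12389 ± 2486 (0.85 ± 0.25) and Eomes 1.11 ± 0.34, each past the threshold adjusted over the list alone. Endothelial genes had positive values in Sox18 (1.11 ± 0.42) and Eng (1.00 ± 0.36), with a list median of 0.07. Hedgehog signalling genes had a median of 0.30, BMP and TGF-beta signalling 0.30, FGF signalling 0.09, imprinted genes -0.04, glycolysis and hypoxia response 0.00, and genes of the differentiated lung -0.35. Hox genes of paralogue groups 6 to 13 had 0.03, immediate early and heat shock genes -0.09, mesothelial and splanchnic markers 0.25, paraxial mesoderm and skeletal muscle markers 0.02 and pancreas and posterior gut markers 0.26. With neural (0.26), mesenchymal (0.18), erythroid (0.15), Notch (0.12), matrix (0.08) and epithelial (-0.03) lists, these are among the 23 lists not called over the whole interval, with adjusted p from 0.0853 to 0.909 in camera of limma. Median and mean differed in sign for pharyngeal and thyroid markers (0.04 and -0.23, with a negative direction in the test), for lung and foregut endoderm regulators (just under 0 and 0.04) and for early embryo genes (just under 0 and 0.21, both with a positive direction in the test). At the second step they differed for retinoic acid, anterior Hox, differentiated lung, respiratory chain and immediate early lists, none of them called. Sex-linked genes were too few for a list test.

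Cardiac and hepatic markers were lower at 26-30 than at 16-20 somites, with an adjusted p = 0.822 with an estimated correlation. Scaling of 16-20 somites replicate 2 is argued against, since over all genes that array exceeded the other arrays of its stage by a median of 0.0577 log2, against 1.40 over the cardiac and hepatic genes. Heart and liver tissue in that pool stays open: 87.5% of the 32 genes were highest in that array among the 3 of its stage, against 38.7% of all genes, and the median change was -0.51 with the array and -0.04 without it, but the array was singled out by these same genes, so these values restate the pattern and decide nothing. Abundant members of the lists on that array included Ttr at 21559, Afp at 7949.8 and Myh6 at 5247. The heart had been dissected away, and the mid-foregut is the stretch in front of the liver. Of the 32 genes, 28 also had signal above the filter in both other arrays, and 4 are in another list. A difference in stage within the pooled embryos stays open and was not tested. The arrays do not name the tissue that made these transcripts. Over the whole interval the liver marker Alb changed by -0.27, where Ttr, Apob and Afp changed by -2.66, -1.74 and -1.31. Other Afp probe sets gave -2.67 and -2.29. Alb and Apob had mean log2 signals of 7.52 and 6.85, against a filter level of 6.66.

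The Y-linked genes Eif2s3y, Kdm5d and Uty had log2 differences of 0.81 ± 0.30, 0.95 ± 0.27 and 0.75 ± 0.24 between 26-30 and 16-20 somites, although other Kdm5d probe sets gave -0.49 and -0.89. A difference of the narrow-range arrays was examined on single arrays. 26-30 somites replicate 3, which is not narrow-range, lay above all 6 earlier arrays in 3 of 3 genes. Its mean log2 signal over these genes was 8.02, against at most 7.70 in the earlier arrays. On 21-25 somites replicate 1, a narrow-range array, that mean was 7.39. These values argue against it, but margins were small, as 8.75 at the lowest 26-30 array against 8.68 for Eif2s3y. More male embryos in the pools of 26-30 somites may account for it, but Xist, which is expressed from the inactive X chromosome, had 0.17 ± 0.68 in its brighter probe set and -1.03 in a dimmer one, which differ in sign and leave it open. With few embryos per pool and 1 array per pool, sex and stage cannot be told apart here for these genes.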
